A study of Homo sapiens with 20 samples.

How the data were processed

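RNA was measured by stranded poly(A)-selected RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after transfection with small interfering RNA (siRNA) against HUWE1 or with non-targeting (NT) siRNA. HUWE1 encodes a large HECT-domain ubiquitin ligase. The labels place 20 libraries in 5 groups of 4: non-targeting and HUWE1 siRNA libraries that carry no set number, called set 1 here, HUWE1 siRNA libraries of sets 2 and 3, and 4 non-targeting libraries shared by sets 2 and 3. What distinguishes the sets is not given in the sources used here. RNA was taken up in Trizol and precipitated with isopropanol, per the labels' protocols.

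The authors deposited TPM values (transcript abundance scaled for transcript length and for the library total) in 2 tables, with set 1 in the first and sets 2 and 3 in the second. The genome build was hg38, per the submitters' processing notes, and the aligner, counter and annotation are not given in the sources used here. Both tables held the same 45372 gene symbols and the values of each library summed to the same total, so the sequencing depth is unknown and no counting interval was computed. Of the symbols, 41180 were found in GENCODE release 29, which is on the same build and gave coordinates, GC content and transcript length. All per-sample columns were used.

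From these values, log2(TPM + 1) was computed, and genes with a TPM of 1 or more in at least 4 libraries of a table were tested with limma 3.58.1 in R 4.3.3, using a moderated variance with a mean trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Set 1 was fitted on its 8 libraries. The second table was fitted as 1 model of 12 libraries, which gave set 2 and set 3 against their shared controls and set 3 against set 2. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. The 2 tables were normalized separately and were never tested together. HUWE1 also had a two-sided exact permutation test of 4 against 4 TPM values, whose smallest p is 0.0286. The 4 libraries of a group are separate biological replicates per the labels.

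Fixed before the data were examined were 31 gene lists of pathways, complexes and cell type markers with 999 entries, of which 989 were found in the tables, 60 of them through an older symbol. Each list with 5 or more tested members was tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. The named genes are HUWE1, the 8 largest increases and 8 largest decreases of each set among called genes with a mean TPM of 5 or more in a group and no overlap between the 4 values of each group, the same for 5 and 5 genes in set 3 against set 2, and up to 4 list members with the smallest p. Clone-type names were passed over. Some list members that this rule names are not reported here. The rule also named up to 10 genes in each direction called in all 3 sets. Only HUWE1 met it, so the same rule was applied to sets 1 and 3 after this had been seen.

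The procedure was tested on simulated data made from each comparison's own means and residuals, with 200 changed genes. For set 1, over 16057 genes with noise correlated between genes as in the data, it recovered 49.2% of the genes changed by 0.25 on the log2 scale, 91.0% at 0.5 and 97.0% at 1. For set 2, over 15860 genes, it recovered 28.4%, 77.6% and 98.5%, and for set 3, over 15860 genes, 53.7%, 86.6% and 98.5%. For set 3 against set 2, over 15860 genes, it recovered 34.3%, 83.6% and 100.0%. Each recovery came from a single simulated dataset. Sets 2 and 3 share their residuals, control means and fit. The gap between their recoveries is therefore variation between simulated datasets and not a difference in power. In 20 simulations per comparison with no changed gene, none called a gene in set 1, set 2 or set 3 against set 2, and 2 called genes in set 3, up to 4226. These simulations also drew sets 2 and 3 from the same model, so their counts do not set the 2 sets apart.

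Alternatives were a pseudocount of 0.1, no filter, a mean TPM of 5 or more, median-of-ratios scaling, quantile normalization, TPM recomputed without mitochondrially encoded genes, limma without the variance trend and with robust variance, the replicate number as a block, only the 2 groups compared, a log2 fold change of 1 or more, and leaving out each library. The bound on what a correction may keep was read with its bootstrap spread only after the values were seen. That spread came from resampling the genes of a list and is about a standard error. It treats genes as independent and holds no variation between libraries. Chosen after seeing the data were removal of each library's GC and length trend, the first within-group component as a covariate, the fit without 2 control libraries, the overlap of sets 1 and 3, removal of the component's gene pattern from the set 3 fold changes, the spread of each list's median under other scalings, and the exact permutation test of each list's mean over the 35 splits of 8 libraries.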

Results

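Gene expression was measured by RNA sequencing in HEK293T cells given siRNA against HUWE1 or non-targeting siRNA, to describe the transcriptional response to HUWE1 knockdown. There were 5 groups of 4 libraries: non-targeting and HUWE1 siRNA in set 1, and HUWE1 siRNA in set 2 and in set 3 with 4 non-targeting libraries shared between them. Each library's TPM values summed to the same total and sequencing depth is unknown. Within groups, the lowest correlation of log2(TPM + 1) values across genes between 2 libraries was 0.980 in the non-targeting libraries of sets 2 and 3 and 0.992 in HUWE1 set 2, the lowest of the other groups. Genes are not independent replicates. Mitochondrially encoded transcripts made up 25.2% ± 0.692 of TPM in the set 1 controls and 17.7% ± 0.762 in the controls of sets 2 and 3 (SD, n = 4 each), in tables that were normalized separately.

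The targeted transcript was lower in every HUWE1 siRNA library than in every control of its table. HUWE1, an X-linked gene encoding a HECT-domain ubiquitin ligase (GRCh38, chromosome X, 53532096 to 53686729, minus strand), fell from 157.2 ± 3.57 to 85.0 ± 1.72 TPM in set 1 (SD, n = 4). In sets 2 and 3 the shared controls held 163.3 ± 3.49 TPM, against 94.6 ± 2.26 in set 2 and 84.8 ± 5.42 in set 3 (SD, n = 4). This left 54.1%, 57.9% and 51.9% of the control level. The log2 fold changes were -0.88 ± 0.025 in set 1, -0.78 ± 0.045 in set 2 and -0.94 ± 0.045 in set 3 (SE), with limma adjusted p of 1.69e-07, 7.45e-06 and 8.17e-07, and the exact permutation p was 0.0286 in each set. Between sets 3 and 2 the difference of -0.16 ± 0.045 did not pass the threshold over all genes (limma adjusted p = 0.134), while the exact permutation test of HUWE1 alone gave p = 0.0286.

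**Figure D1:**
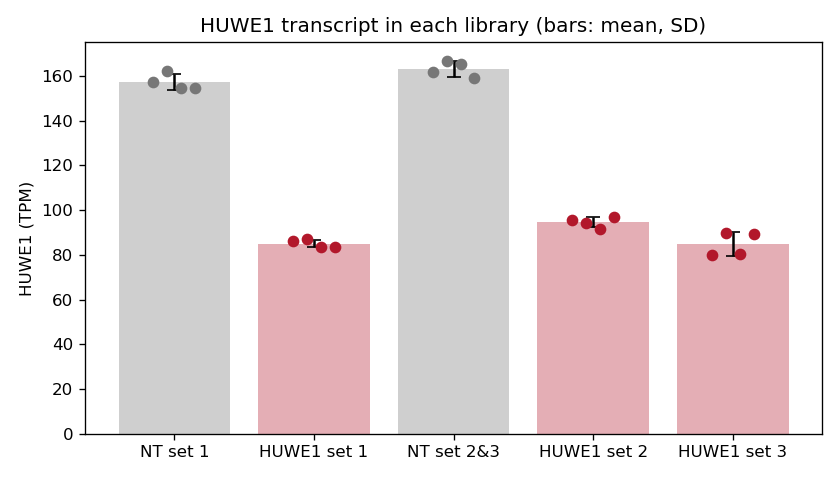
HUWE1 transcript level in TPM for each library (points), with group means (bars) and SD (error bars), for non-targeting (NT, grey) and HUWE1 siRNA (red) groups. The HUWE1 siRNA means lie between 84.8 and 94.6 TPM and the control means at 157.2 and 163.3 TPM; the tables of set 1 and of sets 2 and 3 were normalized separately.

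In set 1, the response was broad and small. Under the rule for named genes, the largest increases were in PLIN5, which coats lipid droplets (4.44 ± 0.433 to 8.65 ± 0.936 TPM; log2 fold change 0.83), and in MIR22HG (0.76), IFI35 (0.64), PLA2G6 (0.55), CCND1, which encodes cyclin D1 (0.54), UNC5C (0.50), BAIAP3 (0.49) and MMP13 (0.48). The largest decreases were in INHBE, an activin subunit (23.1 ± 1.81 to 9.42 ± 2.07 TPM; -1.23), S100P (-1.17), G0S2, an inhibitor of triglyceride lipase (-0.91), ETV7 (-0.87), HIST2H2BE (-0.85), ST20-MTHFS (-0.85), HMOX1, which encodes heme oxygenase (from a mean of 148.8 TPM to 85.9 ± 4.70 TPM; -0.79), and the Mediator subunit MED19 (-0.76). All TPM errors are SD with n = 4. Limma adjusted p for these 16 genes lay between 8.18e-06 and 0.00419. ST20-MTHFS is a readthrough of neighbouring genes and HIST2H2BE belongs to a family of near-identical genes, so their values depend on how reads were assigned. In all, limma called 4863 of 16057 genes, 1983 higher and 2880 lower, of which 5 reached a log2 fold change of 1. The share of higher genes was 40.8%, against 49.0% with median-of-ratios scaling and 50.8% with quantile normalization.

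MYC targets were mostly lower in set 1. Of 40 MYC target genes, mostly nucleolar and biosynthetic, 28 fell and 0 rose (28 and 0 adjusted over the list alone), with a median log2 fold change of -0.13. They included RRP12 (-0.54), which acts in ribosome assembly, the spermidine synthase gene SRM (-0.46), TCOF1 (-0.35) and RCL1 (-0.35). The camera adjusted p was 7.51e-10 at the preset correlation, and the adjusted p was 0.0724 with an estimated correlation. Transcripts of 30 proteins reported as HUWE1 substrates included MYC itself, which fell by 0.18 on the log2 scale, TIAM1 (-0.60) and CDC6 (-0.29). Of this list 8 fell and 4 rose (9 and 5 adjusted over the list alone), and camera did not call it (adjusted p = 0.238; adjusted p = 0.482 with an estimated correlation). Its mean relative to all genes was lower in 4 of 4 HUWE1 libraries than in every control (difference -0.06, exact permutation p = 0.0286, adjusted p = 0.0522), and fry, which does not compare a list with other genes, gave an adjusted p of 2.74e-04.

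Stress response genes driven by ATF4 also fell in set 1. Of 39 members 26 fell and 2 rose (27 and 2 adjusted over the list alone), with a median of -0.18, among them TRIB3 (-0.72), CEBPG (-0.42), PPP1R15A (-0.40) and the amino acid transporter gene SLC7A5 (-0.35). Camera gave an adjusted p of 8.75e-08, and the adjusted p was 0.0724 with an estimated correlation. This fall was not seen in the other sets. In set 2 the median was 0.02, with 0 members called (camera adjusted p = 0.288, exact permutation p = 0.543). In set 3 it was -0.05, with 3 members higher and 1 lower (camera adjusted p = 0.758, exact permutation p = 0.686). E2F targets of DNA replication had 22 of 43 members lower and 2 higher (22 and 2 adjusted over the list alone), with CLSPN (-0.38), E2F2 (-0.37), RRM2 (-0.33) and MCM3 (-0.21) among those that fell. Their camera adjusted p was 8.12e-05, and the adjusted p was 0.151 with an estimated correlation. Of 28 targets of p53, whose protein is bound by large T antigen in this line, 8 fell and 5 rose (8 and 5 adjusted over the list alone), with GDF15 at -0.91 and AEN at -0.41, and camera did not call the list (adjusted p = 0.322). Its mean relative to all genes was lower in 4 of 4 HUWE1 libraries than in every control (difference -0.07, exact permutation p = 0.0286, adjusted p = 0.0522), and fry gave an adjusted p of 0.00846.

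Lysosome and autophagy genes rose in set 1. Of 41 members 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.11. ATP6V0D1, a subunit of the vacuolar proton pump, rose by 0.38, GLB1 by 0.27 and PSAP by 0.25. The camera adjusted p was 5.07e-08, and the adjusted p was 0.0724 with an estimated correlation. Of 74 cytosolic ribosomal protein genes 33 rose and 2 fell (38 and 2 adjusted over the list alone), with RPS25 at 0.27 and RPL13A at 0.26. Of 24 sterol synthesis genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), with TM7SF2 at 0.24 and LSS at 0.19. Their camera adjusted p were 9.15e-09 and 0.0028, and the adjusted p were 0.482 and 0.522 with an estimated correlation. Mitosis genes had 14 of 37 members higher and 3 lower (14 and 3 adjusted over the list alone), with KIF20A at 0.25 and NUSAP1 at -0.43, and nuclear-encoded respiratory chain genes had 16 of 50 higher and 3 lower (17 and 4 adjusted over the list alone), with COX6C at 0.25. Their camera adjusted p were 0.00234 and 0.00197, and the adjusted p was 0.482 for both with an estimated correlation. Histone genes had 7 of 27 members lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.00587, and adjusted p = 0.522 with an estimated correlation).

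Of 9 fibroblast markers 4 rose and 1 fell in set 1 (5 and 2 adjusted over the list alone), with COL3A1 at 0.28, MMP2 at -0.22 and a median of 0.12. Camera did not call the list (adjusted p = 0.200; adjusted p = 0.482 with an estimated correlation), its mean relative to all genes was higher in 4 of 4 HUWE1 libraries than in every control (difference 0.13, exact permutation p = 0.0286, adjusted p = 0.0522), and fry gave an adjusted p of 0.0188.

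Camera at the preset correlation called 11 lists in set 1, and 4 of the 35 splits of these libraries, the labelled one included, gave as many. By the exact permutation test of each list's mean against all genes, 17 of 31 lists reached the smallest possible p of 0.0286, where 0.886 are expected by chance; their Benjamini-Hochberg adjusted p was 0.0522. In set 2 this held for 1 of 30 lists, in set 3 for 6 of 30 and for set 3 against set 2 for 5 of 30, where 0.857 are expected in each, with lowest adjusted p of 0.684, 0.143 and 0.172. Within a comparison all lists were tested on the same libraries and splits, so these lists are not independent results. How many lists reach the smallest p in the other splits was not computed.

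**Figure D2:**
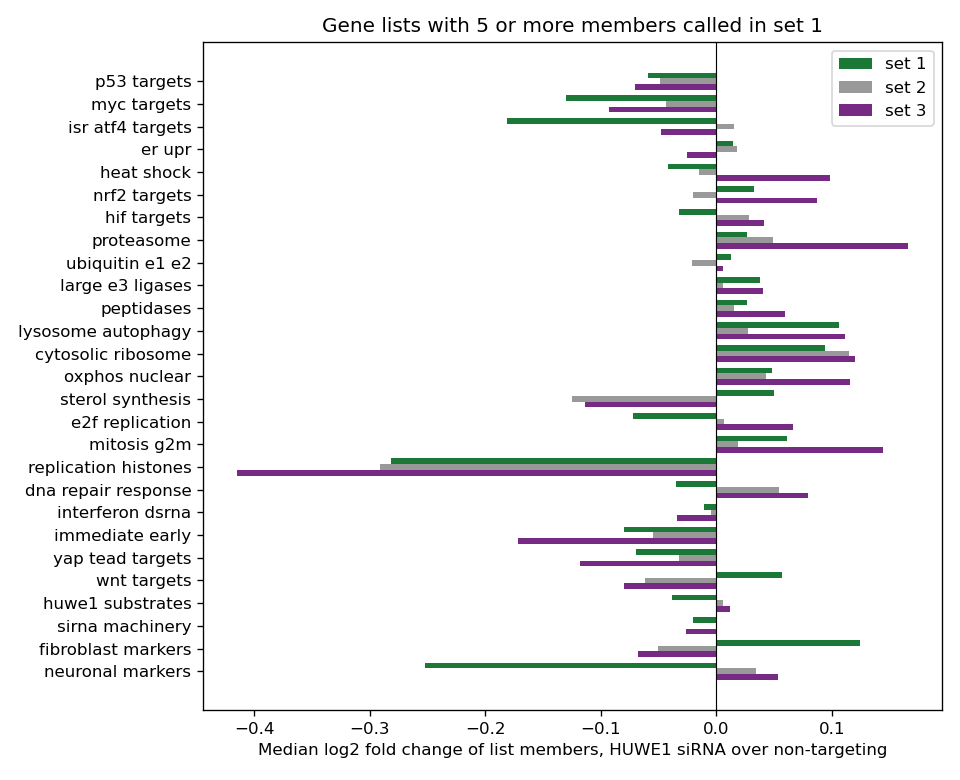
Median log2 fold change (HUWE1 siRNA over non-targeting siRNA, log2(TPM + 1) scale) of the members of each gene list with 5 or more members called in set 1, for set 1 (green), set 2 (grey) and set 3 (purple). MYC targets lie at -0.13, -0.04 and -0.09, and lysosome and autophagy genes at 0.11, 0.03 and 0.11; the bars carry no error, and sets 2 and 3 share controls.

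In set 2, the HUWE1 transcript fell and almost nothing else passed the test. Limma called 2 of 15860 genes, HUWE1 and the Mediator subunit MED4, which fell from 82.4 ± 4.60 to 63.0 ± 2.32 TPM (SD, n = 4; log2 fold change -0.38, limma adjusted p = 0.0347). At an unadjusted limma p under 0.05 there were 1401 genes. Limma called 0 members of the fixed lists over all genes. By the sign of their fold changes, 74 of 74 cytosolic ribosomal protein genes were positive, with a median of 0.12, 13 of 13 mitochondrially encoded genes were negative, with a median of -0.09, and 19 of 22 histone genes were negative, with a median of -0.29. Their camera adjusted p were 2.56e-25, 0.00437 and 5.1e-04, the adjusted p were 0.757, 0.757 and 0.893 with an estimated correlation, and 0 members were called adjusted over the list alone. Without non-targeting replicate 1 the histone list was no longer called (median -0.10, adjusted p = 0.0913), and the mitochondrially encoded list was not called without non-targeting replicate 2 (-0.08, 0.0721) or HUWE1 set 2 replicate 4 (-0.07, 0.0774), without the filter (0.127) or with quantile normalization (0.142). Histones were not called at a mean TPM of 5 or more (0.0627). Among 24 sterol synthesis genes, 0 were higher and 6 lower adjusted over the list alone, with DHCR7 at -0.24, and the median was -0.12 (camera adjusted p = 3.59e-07, and adjusted p = 0.757 with an estimated correlation). MYC targets had a median of -0.04 and lysosome and autophagy genes one of 0.03 (camera adjusted p 0.0766 and 0.285). Relative to all genes, the mean of MYC targets was lower in 4 of 4 HUWE1 libraries of set 2 than in every control (difference -0.04, exact permutation p = 0.0286, adjusted p = 0.684). By the same test, the exact permutation p was 0.143 for cytosolic ribosomal protein genes and 0.114 for mitochondrially encoded genes. It was 0.257 for histone genes and 0.257 for sterol synthesis genes. Genes of a list vary together, so the sign counts are not independent observations. Leaving out any of 7 of the 8 libraries, all but non-targeting replicate 1, left 1 call, and other splits of the 8 libraries gave up to 3189.

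In set 3, the largest increases under the same rule were in the long noncoding RNAs LINC02154 (9.40 ± 3.50 to 19.5 ± 1.46 TPM; log2 fold change 1.03) and LINC01411 (0.96), the transcription factor gene KLF2 (0.80), PBLD (0.77), the hyaluronan receptor gene CD44 (0.77), SYCE3 (0.71), RWDD2B (0.68) and WDR31 (0.68). The largest decreases were in DEPP1 (-0.96), MAP4K1 (-0.93), HIST1H2BD (-0.85), HIST1H2BK (-0.81), DDIT4, which encodes an inhibitor of mTORC1 (1475 ± 378.0 to 828.9 ± 88.6 TPM; -0.80), TRMT61A (-0.77), ID1 (-0.77) and HIST1H4J (-0.73). TPM errors are SD with n = 4, and limma adjusted p lay between 0.00065 and 0.035. These p come from the fit of 12 libraries, which also holds HUWE1 set 2. With only the 2 groups compared, PBLD, SYCE3, RWDD2B, MAP4K1, HIST1H2BD, HIST1H2BK, TRMT61A, ID1 and HIST1H4J lost their call (limma adjusted p 0.057 to 0.0715). Of the 31 genes besides HUWE1 named by rule in set 3, those shared with set 1 included, 23 lost their call under some alternative, and 0 changed direction. Across genes, the set 3 fold changes correlated at 0.69 with the gene scores of the first component of the deviations from group means, on which non-targeting replicates 1 and 4 lay farthest apart, and the set 2 fold changes at 0.53. The scores were 0.901 for PBLD, 0.888 for LINC02154, -0.944 for DEPP1 and -1.12 for MAP4K1, against 0.0998 for CD44 and 0.0315 for KLF2. Limma called 1839 of 15860 genes, 1181 higher and 658 lower. This count was not stable: another split of the same 8 libraries gave 3038. It was 5878 without non-targeting replicate 4, and 745, 396 and 257 without non-targeting replicates 1, 2 and 3. Without HUWE1 set 3 replicates 1, 3 and 4 it was 533, 163 and 167. With only the 2 groups compared it was 360, and without the filter 698. The share of higher genes was 64.2%, against 48.1% with median-of-ratios scaling, 52.4% with quantile normalization and 44.4% without mitochondrial genes.

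Among the fixed lists in set 3, lysosome and autophagy genes had 15 of 41 members higher and 0 lower (19 and 1 adjusted over the list alone), including ATP6V0D1 (0.44) and OPTN (0.42). MYC targets had 10 of 40 lower and 0 higher (18 and 0 adjusted over the list alone), including WDR74 (-0.41), SRM (-0.41), MYBBP1A (-0.32) and the dyskerin gene DKC1 (-0.25). The camera adjusted p were 1.94e-05 and 5.93e-04, and the adjusted p was 0.355 for both with an estimated correlation. Proteasome genes had 5 of 36 higher and 0 lower (14 and 0 adjusted over the list alone), with PSMC1 at 0.34 and PSMD6 at 0.30. Their median score on the first within-group component was 0.308, and removal of that component's gene pattern was not run for this list. Sterol synthesis genes had 5 of 24 lower and 0 higher (5 and 0 adjusted over the list alone), with INSIG1 at -0.45 and DHCR7 at -0.28, and E2F targets had 4 of 43 higher and 0 lower (8 and 0 adjusted over the list alone), with PRIM1 at 0.46 and CCNE2 at 0.35. The camera adjusted p of these 3 lists were 1.37e-05, 0.00353 and 0.00199, and the adjusted p were 0.730, 0.730 and 0.658 with an estimated correlation. Without non-targeting replicate 4 the sterol synthesis list was no longer called (median -0.08, adjusted p = 0.181). Cytosolic ribosomal protein genes had 14 of 74 higher and 0 lower (31 and 0 adjusted over the list alone), with RPL9 at 0.27, and mitochondrially encoded genes had 4 of 13 lower and 0 higher (11 and 0 adjusted over the list alone), with MT-ND2 at -0.37. Camera gave adjusted p of 9.78e-10 and 7.9e-05, and the adjusted p were 0.730 and 0.591 with an estimated correlation. Of 29 p53 targets 3 rose and 1 fell (4 and 1 adjusted over the list alone), with CDKN1A at 0.55, and camera did not call the list (adjusted p = 0.879). Camera called 13 lists in set 3, and 2 of the 35 splits, the labelled one included, gave as many. Histone genes, whose main transcripts lack a poly(A) tail, summed to 337.1 TPM in non-targeting replicate 1 and to 195.1 ± 98.2 TPM over the 4 controls, against 106.6 ± 6.56 in set 3 (SD, n = 4).

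HUWE1 was the only gene called in all 3 sets. Over the 15296 genes tested in both tables, sets 1 and 3 shared 378 higher genes where independent lists would share 148.8, and 314 lower genes where 119.5 would be shared, and 92 genes were called in opposite directions where 296.7 would be. The shared higher genes, ranked by the smaller of the fold changes in sets 1 and 3, began with CYBA (0.44 in set 1 and 0.43 in set 3), RWDD2B (0.43 and 0.68), RHBDF1 (0.41 and 0.53), ATP6V0D1 (0.38 and 0.44), COL6A2, FAM234A, EFR3A, EPHX2, CIRBP and EVI5L. The lower genes other than HUWE1 began with DDIT4 (-0.73 and -0.80), DEPP1 (-0.68 and -0.96), MED19 (-0.76 and -0.61), MAP4K1 (-0.53 and -0.93), TRMT61A (-0.52 and -0.77), MRM1, CCDC86, ADO, DHX37 and RRP12. With only the 2 groups compared, the set 3 call was lost for RWDD2B, FAM234A, EPHX2, CIRBP and EVI5L. It was also lost for MAP4K1, TRMT61A, CCDC86, ADO, DHX37 and RRP12. Limma adjusted p of these genes then lay between 0.0546 and 0.0852. The shared count of 692 was 289, 188, 122 and 1963 without non-targeting replicates 1, 2, 3 and 4 of sets 2 and 3, and 209, 79 and 81 without HUWE1 set 3 replicates 1, 3 and 4. Another split of the set 3 and control libraries gave 1072. The fold changes of sets 1 and 3 correlated at 0.38 across genes, which are not independent replicates. Those of sets 1 and 2 correlated at 0.29. Of the genes called in set 1, 71.7% had the same sign in set 2, against 61.9% of all genes. Agreement of set 2 with set 1 was not computed in other splits.

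The fold changes of sets 2 and 3, taken against the same controls, correlated at 0.70 across genes. Simulated unchanged groups against shared controls gave 0.49 on average, from -0.46 to 0.89 over 50 simulations, so the observed value lay within what no effect can give. The covariance of 0.020 also lay within the simulated range of -0.00323 to 0.0361, with a mean of 0.00817. With the controls split so that no library was shared, the correlation lay between -0.10 and 0.46 over 6 splits.

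Between sets 3 and 2 a small number of genes passed the limma test over all genes. At an unadjusted limma p under 0.05 there were 2507 genes. The 4 values of each group did not overlap for 13.2% of genes, where 2.86% are expected by chance. Genes are not independent, so these shares do not measure how many genes differed. CDKN1A, which encodes the cell cycle inhibitor p21, was at 64.7 ± 2.85 TPM in set 3 and 42.5 ± 0.755 in set 2 (SD, n = 4; log2 difference 0.59, limma adjusted p = 2.40e-04). LINC01411 (0.67), KLF2 (0.67), HSPB8, a small heat shock protein gene (0.56), and HIGD1A (0.49) were also higher in set 3. LINC01786 (-0.54), MED19 (-0.52), SRPRA (-0.50), PIM2 (-0.50) and INSIG1, which encodes a regulator of sterol synthesis (-0.49), were lower. The call was lost for INSIG1 without any 1 of the 8 libraries (adjusted p 0.0768 to 0.131), and for LINC01411 (0.0756 to 0.117) and HIGD1A (0.0508 to 0.092) without any but HUWE1 set 2 replicate 1. For LINC01786 it was lost without HUWE1 set 2 replicates 2, 3 or 4 or HUWE1 set 3 replicate 1 (0.0516 to 0.0673). Without the filter it was lost for LINC01411 (0.0678) and INSIG1 (0.0769), and without the variance trend for INSIG1 (0.0537). Limma called 82 of 15860 genes, 49 higher and 33 lower in set 3. This was 335 with only these 2 groups in the fit. It was 29, 21 and 22 without HUWE1 set 2 replicates 2, 3 and 4, and 21, 34, 20 and 26 without HUWE1 set 3 replicates 1, 2, 3 and 4. Lysosome and autophagy genes had a median difference of 0.11 and MYC targets one of -0.06, with camera adjusted p of 1.23e-06 and 0.00104 and an adjusted p of 0.259 for both with an estimated correlation; 0 members of either list were called over all genes (10 higher and 0 lower, and 0 higher and 2 lower, adjusted over the list alone). Mitochondrially encoded genes had a median difference of -0.13, negative in 12 of 13 genes, with 0 members called over all genes or adjusted over the list alone. The camera adjusted p was 0.0036, the adjusted p was 0.668 with an estimated correlation, and the list was not called without the filter (0.101) or with quantile normalization (0.174). The share of higher genes was 59.8%, against 49.4% with median-of-ratios scaling and 49.3% without mitochondrial genes.

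**Figure D3:**
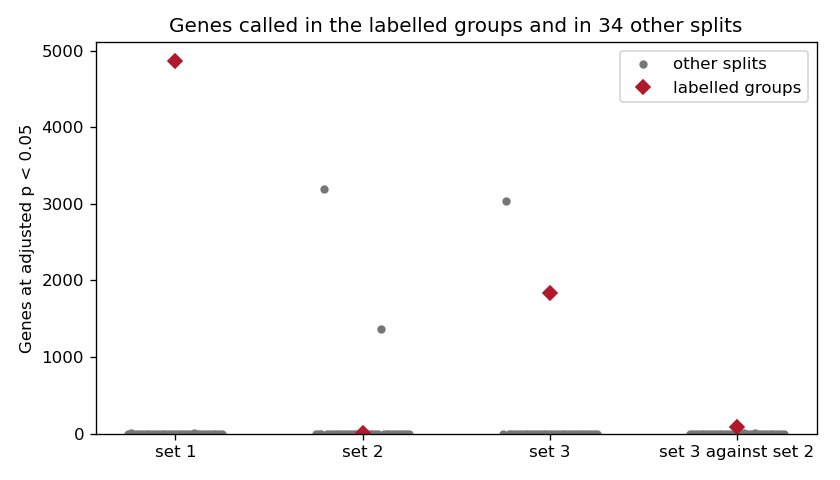
Number of genes at an adjusted p under 0.05 in each comparison for the labelled groups (red diamonds) and for the 34 other splits of the same 8 libraries into 4 and 4 (grey points). In set 1 the labelled groups gave 4863 genes and no other split more than 1, whereas other splits reached 3189 in set 2 and 3038 in set 3.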

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

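The tests of the 2 outlying control libraries, the component gene pattern, the single medians under other scalings, each list apart and the permutation of each list were chosen only after the results they bear on were seen, and the bounds on what a correction keeps were read with their bootstrap spread only then. The bootstrap spreads below are over the genes of a list, are about a standard error and hold no variation between libraries.

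With the labelled groups of set 1, 4863 genes were called, and 1 of the 35 splits, the labelled one, gave as many (highest other split 1). For set 3 against set 2, 82 genes were called and 1 of the 35 splits gave as many (highest other 1). Both results argue against chance. They cannot exclude it, because 35 splits give no exact permutation p under 0.0286 and several comparisons were tested. Without 1 library the 82 calls became 20 to 68. For set 3, 2 of the 35 splits gave as many as its 1839 genes (highest other 3038), and for set 2, 3 gave as many as its 2 genes (highest other 3189), so chance cannot be excluded. Splits with that many calls point to a structure among the libraries of sets 2 and 3. The 692 genes shared by sets 1 and 3 were matched by 2 of the 35 splits (highest other 1072), and so was the correlation of 0.38 between their fold changes (highest other 0.392), so chance cannot be excluded for either. The number of lists past the preset camera threshold was matched by 4 of 35 splits in set 1 (11 lists, highest other 12), 31 in set 2 (5, highest other 14), 2 in set 3 (13, highest other 13) and 4 for set 3 against set 2 (10, highest other 11), so these list counts cannot be set apart from chance. In set 1 the other splits that matched kept 3 of the 4 libraries of each group together, so they hold part of the labelled contrast. Set 1 splits with 2 libraries of each group on each side gave at most 6 lists. The comparison of list counts is therefore a weak test.

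Set 2 gave 2 calls and set 3 gave 1839 against the same controls. Non-targeting replicates 1 and 4 lay farthest apart on the first component of the deviations from group means, which held 39.6% of the within-group variance in that table; without both, set 2 still gave 2 calls and set 3 gave 3245, which argues against these libraries having hidden a set 2 response of that extent. With the component as a covariate set 2 gave 1641 calls, but the covariate is computed from the residuals, leaves every fold change as it was and lowers the residual variance alone; with no changed gene simulated, it called up to 5669 genes, so that count decides nothing. A smaller loss of HUWE1 in set 2 stays open: over 4766 genes called in set 1, HUWE1 not among them, the slope of set 2 on set 3 was at most 0.782 over 6 control splits, under the ratio of 0.832 between the HUWE1 fold changes, but noise in set 3 lowers that slope and the inverse regression reached 3.17. What differs between the sets by design was not tested.

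MYC targets were lower, and lysosome and autophagy genes higher, in sets 1 and 3, each with the most extreme of the 35 splits (exact permutation p = 0.0286, adjusted p = 0.0522 in set 1 and 0.143 in set 3); in set 2 this held for MYC targets too (difference -0.0444 relative to all genes, exact permutation p = 0.0286, adjusted p = 0.684) but not for lysosome and autophagy genes (0.0248, exact permutation p = 0.457). Under 3 other scalings all 12 medians kept their sign by more than their bootstrap spread, which argues against a common scaling shift as the whole cause, though without mitochondrial genes the lysosome median in set 3 kept 0.728 of its size and that of MYC targets 1.34; the gap between the lists, tested first, kept at least 0.982, but a factor per library moves both lists alike, so the gap decides nothing. GC content or transcript length as the whole cause is argued against in set 1, where the medians kept at least 0.915 with these trends removed (spread 0.0836), and for lysosome and autophagy genes in set 3 (1.26, spread 0.184), for which the component's gene pattern is argued against too (0.958, spread 0.184). For MYC targets in set 3, GC content or length (0.858, spread 0.254) and the component's gene pattern (0.788, spread 0.616) cannot be told apart from an effect of HUWE1 siRNA, because the spreads reach under the bound of 0.75. The component as a covariate kept 1 of each median by its construction, and a response of these lists to HUWE1 siRNA is a hypothesis.

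Sterol synthesis genes were higher in every HUWE1 library of set 1 than the control mean (mean log2 difference 0.0809) and lower in every library of set 3 (-0.0974), and E2F targets were lower in set 1 (-0.114) and higher in set 3 (0.0898); the difference between the tables was not tested. Relative to all genes, the differences of sterol synthesis genes were 0.101 in set 1 (exact permutation p = 0.0286) and -0.0981 in set 3 (exact permutation p = 0.343, 12 of 35 splits as large), and those of E2F targets -0.0935 and 0.0890 (exact permutation p = 0.0286 each). The camera call of sterol synthesis genes in set 3 was lost without non-targeting replicate 4 (median -0.0778, adjusted p = 0.181), and in set 2, against the same controls, their median was -0.12. For each list 6 of 6 medians kept their sign under 3 other scalings by more than their bootstrap spread over genes. This argues against a common scaling shift as the whole cause for sterol synthesis genes, whose median in set 1 grew to 1.69 of its size with quantile normalization. For E2F targets the margin was small. Their median in set 3 kept 0.527 of its size without mitochondrial genes (0.0351, spread 0.0264), so a scaling shift cannot be excluded there. With the component's gene pattern removed the sterol median in set 3 grew to 1.67 of its size (spread 0.731), which argues against that pattern, whereas the E2F median kept 0.828 (spread 0.260), so for E2F targets it cannot be told apart because the spread reaches under the bound of 0.75 (the component as a covariate again kept 1 of each median by construction).

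The means of other lists lay on opposite sides of the control mean in every HUWE1 library of sets 1 and 3, in that order, with no test of the difference: heat shock genes (-0.0177 and 0.0803), DNA repair genes (-0.0510 and 0.0641), Wnt targets (0.0492 and -0.0655), skeletal muscle markers (-0.0352 and 0.0548) and neuronal markers (-0.203 and 0.0328). The tested members were not the same in the 2 sets for skeletal muscle markers (9 and 5 genes) and neuronal markers (10 and 11 genes). Against all genes, heat shock genes in set 1 had a difference of 0.00230, of the same sign as in set 3. Against all genes, the exact permutation p in sets 1 and 3 were 0.886 and 0.114 for heat shock genes, 0.0286 and 0.0286 for DNA repair genes, 0.0286 and 0.0571 for Wnt targets, 0.514 and 0.114 for skeletal muscle markers and 0.0286 and 0.314 for neuronal markers. LINC01411 (-0.39 and 0.96) and HSPB8 (-0.20 and 0.60) also differed in sign between sets 1 and 3, and this difference was not tested.

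Between sets 3 and 2 the difference itself passed the limma test for 82 genes. The named ones were LINC01411 (0.67), KLF2 (0.67), CDKN1A (0.59), HSPB8 (0.56), HIGD1A (0.49), LINC01786 (-0.54), MED19 (-0.52), SRPRA (-0.50), PIM2 (-0.50) and INSIG1 (-0.49), of which LINC01411, HIGD1A, LINC01786 and INSIG1 lost their call in fits without 1 library (adjusted p up to 0.117, 0.092, 0.0673 and 0.131).

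Of 186 groups of 4 values, 6 held a library far from the others, where chance gives about 1 in 20 (9.3). Histone genes summed to 167.8 TPM in HUWE1 set 2 replicate 4. MIR22HG was at 3.01 and CCND1 at 8.20 TPM in non-targeting set 1 replicate 2. ETV7 was at 7.41 TPM in non-targeting set 1 replicate 3. CYBA was at 37.1 TPM in HUWE1 set 3 replicate 2, and RHBDF1 at 9.22 TPM in non-targeting replicate 4 of sets 2 and 3.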

How the results depend on the processing

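The covariate, the GC and length correction, the fit without 2 control libraries and the overlap of sets 1 and 3 were chosen after seeing the data. HUWE1 fell in all 3 sets under every alternative run, except that it does not reach a log2 fold change of 1, with leave-one-out log2 fold changes of -0.889 to -0.864 in set 1, -0.794 to -0.766 in set 2 and -0.967 to -0.912 in set 3. Except at a log2 fold change of 1 or more (5 genes), the set 1 count stayed within 1.5 times its value, from 3640 to 4675 without a library. Set 2 gave 1 call with median-of-ratios scaling, without the variance trend and with only the 2 groups compared, 6 without mitochondrial genes, 0 at a log2 fold change of 1 or more and 1 to 2 without a library. Set 3 gave 698 without the filter, 360 with only the 2 groups compared, 4 at a log2 fold change of 1 or more, 3245 without 2 control libraries and 163 to 5878 without a library. Set 3 against set 2 gave 42 without the filter, 335 with only the 2 groups compared, 0 at a log2 fold change of 1 or more, 219 with the GC and length trend removed and 20 to 68 without a library. The genes called in all 3 sets were 2 with quantile normalization and without mitochondrial genes. They were 0 at a log2 fold change of 1 or more and 1 to 1 without a library. Of the 1959 higher and 2808 lower set 1 genes tested in both tables, 3081 had the same sign in sets 2 and 3. No threshold was applied in those sets. Sets 2 and 3 share controls and had the same sign for 78.0% of all genes, so they are not separate replications. Sets 1 and 3 shared 231 genes without the filter, 155 with only the 2 groups compared, 0 at a log2 fold change of 1 or more, 1175 without 2 control libraries and 79 to 1963 without a library. The cause was not tested.

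With the first within-group component as a covariate the counts were 1641 in set 2, 6718 in set 3, 3237 for set 3 against set 2, 716 in all 3 sets and 2415 in sets 1 and 3. These are not evidence of more changed genes: the covariate comes from the residuals, and with no changed gene simulated the same fit called up to 5669 genes in set 2, 6557 in set 3 and 4981 for set 3 against set 2.

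Across all genes the replicate number did not pair the libraries: correlations of same-numbered deviations ran from 0.000215 to 0.0521 in set 1, -0.481 to 0.0389 in set 2 and -0.0266 to 0.407 in set 3, and 1, 0 and 1 of 4 numbers matched best with their own. On the first within-group component of set 1, however, loadings rose with replicate number in both groups. They ran from -0.611 to 0.443 in the controls and from -0.230 to 0.295 with HUWE1 siRNA. An order effect shared by both groups was not tested. With the number as a block the counts were 4597 in set 1, 1 in set 2, 693 in set 3, 17 for set 3 against set 2, 1 in all 3 sets and 264 in sets 1 and 3.

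Of 35 named genes besides HUWE1 in set 1, none lost its call over 663 values. In set 3, 23 of 31 lost it under some alternative (158 of 648 values), in set 2 MED4 in 12 of 21, and for set 3 against set 2, 6 of 10 (34 of 199). None changed sign. Of the lists past the camera threshold, 2 of 11 lost their call under some alternative in set 1, 3 of 5 in set 2, 5 of 13 in set 3 and 5 of 10 for set 3 against set 2. Of these, nuclear-encoded respiratory chain genes in set 2 turned from higher to a median of -0.00281 without non-targeting replicate 1 (adjusted p = 0.665), the lowest of -0.00281 to 0.0823 without a library. In the main fit of set 2 that list had a camera adjusted p of 0.0228. The adjusted p was 0.893 with an estimated correlation, and the exact permutation p was 0.6. TPM keeps no depth, so no limit from depth was computed.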

Other observations

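The Mediator subunits were looked at together only after the values of MED19 and MED4 were seen.

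MED19 and MED4 are subunits of Mediator, the complex that links transcription factors to RNA polymerase II; both fell in set 1, MED4 fell in set 2 and MED19 fell in set 3. MED19 fell from 39.6 ± 2.17 to 22.9 ± 1.26 TPM in set 1 and from 35.5 ± 3.62 to 22.9 ± 1.64 TPM in set 3, and stood at 33.1 ± 1.67 TPM in set 2 (SD, n = 4; limma adjusted p 1.35e-05, 0.00199 and 0.677). MED4 fell from 61.2 ± 2.59 to 51.9 ± 2.37 TPM in set 1 and from 82.4 ± 4.60 to 63.0 ± 2.32 TPM in set 2, and stood at 86.2 ± 3.77 TPM in set 3 (SD, n = 4; limma adjusted p 0.00249, 0.0347 and 0.353). The set 2 call of MED4 was lost without any 1 library but non-targeting replicate 1 (adjusted p 0.0567 to 0.191), with median-of-ratios scaling (0.0585), quantile normalization (0.0865), no variance trend (0.0661) and only the 2 groups compared (0.343), with log2 fold changes of -0.36 to -0.43 over these and the other alternatives. The differences between sets 3 and 2 themselves passed the limma test, at -0.52 for MED19 (adjusted p = 0.0086) and 0.45 for MED4 (adjusted p = 0.00318). A candidate explanation, a fall of the whole complex, predicts that the other subunits fall too; the median of the other 31 was 0.0228 in set 1, where 4 rose and 7 fell, which argues against it. Whether siRNA sequence matches played a part was not analysed here.

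Neuronal and growth response genes made up further groups in set 1. Of 10 neuronal markers, partly expressed by this line, 4 fell and 1 rose (6 and 1 adjusted over the list alone), including the neurofilament genes NEFM (-0.60) and NEFL (-0.29), INA (-0.39) and SNAP25 (-0.40). Of 29 immediate early genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), including DUSP1 (-0.47), KLF10 (-0.38), JUND (-0.32) and SRF (-0.24). The camera adjusted p were 0.0288 and 0.0397, and the adjusted p were 0.216 and 0.540 with an estimated correlation. The exact permutation p of their means relative to all genes were 0.0286 and 0.0857 (adjusted p 0.0522 and 0.133). For immediate early genes 3 of the 35 splits gave a difference as large. The call of the neuronal markers was lost at a mean TPM of 5 or more (median -0.126, adjusted p = 0.150), without the filter (-0.0735, 0.0670) and without non-targeting set 1 replicate 2 (-0.215, 0.0549). That of the immediate early genes was lost without the variance trend (adjusted p = 0.0572), with the component as a covariate (0.0581), and without non-targeting set 1 replicate 1 (0.0813), non-targeting set 1 replicate 3 (0.0647) or HUWE1 set 1 replicate 4 (0.05).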
